A study of Callithrix jacchus with 3 samples.

How the data were processed

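RNA was measured by sequencing in 3 libraries of 1 group of common marmoset (Callithrix jacchus) cells, called EPSC-like here after the submitters' design text, where EPSC stands for extended pluripotent stem cell. Per the labels' protocols, total RNA was taken with an RNeasy Mini Kit and made into libraries by an Illumina protocol. Per the submitters' processing notes, the authors used Trim Galore 0.4.0, STAR 2.5.3a and featureCounts 1.5.2. The genome build, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here. The deposited values are whole-number counts per Ensembl gene ID, 1 file per library, with no normalization by the authors. Without a stated treatment of shared reads, levels of genes with close copies or many pseudogenes, such as POU5F1, NANOG, GAPDH, PTMA, HSP90AA1 and the ribosomal protein genes, are uncertain. Overlapping and antisense genes cannot be told apart without the strand setting.

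The replicate numbers came from the sample titles, which are alike in all else. The libraries may therefore share 1 origin, such as 1 line, and the levels may not hold for other lines. No label says that the 3 libraries came from separate cultures, so p-values over the 3 libraries measure only the spread between these libraries, which may be technical. P-values that compare a gene list with other genes take genes as units, and those for a pair of libraries take counts. Neither of these measures the spread between samples. There was no control group, and no test between conditions was made. The total counts were 52327369, 55224475 and 40593244 in replicates 1, 2 and 3. The limit that 0 counts allow, taken as 3 counts, was 0.0573, 0.0546 and 0.0736 CPM (counts per 1000000 counts). Such limits cover counting error only, and the reads carry no molecular identifiers, so that error may be larger than the limits allow. The intervals given for shares of genes take the genes as independent.

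Each file listed 30811 genes, of which 12660 had a symbol in the name table used. All rows were gene IDs. The 28 gene lists were fixed before the data were examined. They held 418 entries for 392 different genes, of which 264 matched a symbol. Genes without a match are not counted as absent. Some genes and 1 list are not reported here. Lists overlap, and their names describe the use for which markers were collected. The lists were core, naive and primed pluripotency, 8-cell stage and genome activation, trophectoderm and trophoblast, primitive endoderm, amnion, primitive streak and mesoderm, definitive endoderm, neuroectoderm, germ cell, mesenchyme and fibroblast, blood and endothelium, and cardiac and skeletal muscle. The others described here were Wnt targets, nodal and activin, LIF and STAT3, FGF and ERK, BMP targets, Hippo, DNA methylation, glycolysis, mitochondrial respiration, cell cycle, stress, interferon and housekeeping genes.

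Counts were scaled to CPM with TMM factors of edgeR 4.0.16 (R 4.3.3, limma 3.58.1). CPM does not correct for gene length, so levels of different genes compare only roughly. Each of the 23432 genes with at least 1 count was tested against 1 CPM with the edgeR quasi-likelihood F statistic of an intercept-only model with trended dispersion, two-sided. The function glmQLFTest accepts no model of 1 column, so the F statistic was computed from the deviances of glmQLFit, with the Poisson p-value as a lower bound for genes of low variance. P-values were adjusted by Benjamini-Hochberg, and a gene was called above or below 1 CPM at an adjusted p under 0.05. The prior degrees of freedom were 4.68. They were infinite in the 4 alternatives fitted on 2 libraries, which therefore took each gene's spread from the trend alone and give p-values that are too small for the most variable genes. Lists were compared with all other genes that have a symbol by Fisher's exact test, two-sided, with Benjamini-Hochberg adjustment over the 28 lists. That test takes genes as independent draws, which members of a list are not. Odds ratios had 0.5 added to each cell. That choice was made after the conditional estimate of the test was seen to be infinite for lists whose members were all above the level, and it leaves the p-values as they were. List medians were taken over log2 CPM with a prior count of 0.5, and set against 10000 random lists of the same size. Differences of list medians within a library were tested by an exact two-sided sign-flip permutation test, whose smallest p with 3 libraries is 0.25. Pairs of libraries were compared per gene by an exact conditional binomial test with Benjamini-Hochberg adjustment, which compares those libraries and no conditions. The common biological coefficient of variation came from edgeR on the 15716 genes that passed filterByExpr. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

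On simulated counts for 23432 genes, the test against 1 CPM called 100% of genes set at 0.25 CPM, 88% at 0.5 CPM, 92% at 2 CPM and 100% at 4 CPM. It called 6.5% of genes set at 1 CPM. The counts for this test were drawn independently for 3 libraries at the trended dispersion. These shares thus take no account of a gene's own spread or of replicate 3 standing apart, and may not carry over to the real libraries. In the same number of genes, the pair test called 89% of genes changed 1.5-fold and 0.0344% of unchanged genes. Those pairs were drawn with Poisson counts, the noise that the pair test assumes, so the low share of false calls was set by design. The real libraries varied more, so that share does not carry over to them.

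Genes were named by a rule fixed before the data were examined. It took from each list the 3 matched members of highest mean CPM and the tested member of lowest mean, 19 fixed marker genes, the 10 genes of highest mean CPM, and the 10 genes of largest tagwise dispersion among those with a mean of at least 50 counts. Of the 10 most abundant genes 5 had no symbol, and of the 10 of largest dispersion 7. Of the fixed markers, DPPA3, DNMT3L, GATA3 and SOX17 had no matching symbol. A further 9 tested list members, ESRRB, ARGFX, MAP2, VWF, NKD1, MIXL1, TBX6, JAK2 and LIFR, and members with no counts were named after their values were seen, to complete small counts.

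The alternatives chosen before the data were examined were DESeq2 1.42.0 size factors, total counts without a scaling factor, the DESeq2 Wald test, levels of 0.5 and 2 CPM, other count filters, library sizes without the 10 most abundant genes, a prior count of 2, list means, a 1.5-fold minimum between libraries, and leaving out each replicate. The DESeq2 Wald test was set up again after its first output was seen, with size factors scaled to a geometric mean of 1. Genes of the mitochondrial genome carry no symbol in the name table, so they stayed in the library sizes. Chosen after seeing the data were the sum of replicates 1 and 2 as 1 library, counts halved, and the conditional odds ratio.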

Results

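Gene expression was profiled by RNA sequencing in 3 libraries of EPSC-like cells. Per the study's title, the cells came from attempts to turn embryonic stem cells of the common marmoset, a small New World monkey, into extended pluripotent stem cells. Such cells are described in other species as able to contribute to embryonic and extraembryonic tissues. The 3 libraries form 1 group, with no parental or control cells, so the question that the data can address is which genes these cells express and how far the libraries vary. Total counts ranged from 40593244 in replicate 3 to 55224475 in replicate 2. Between 21076 and 21287 genes had at least 1 count in a library.

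Of the 23432 genes tested, 13129 were called above 1 CPM and 8851 below it, and 1452 were not distinguished from it (edgeR quasi-likelihood F statistic, Benjamini-Hochberg adjusted). A further 7379 genes had no counts in the 3 libraries. Among genes with a symbol, 75.3% were above 1 CPM. The genes of highest mean level that have a symbol were PTMA, HSP90AA1, EEF2, EEF1G and DNMT3B. PTMA, which encodes prothymosin alpha, stood at 7326 ± 844 CPM (SD, n = 3). The chaperone gene HSP90AA1 stood at 6938 ± 1237 CPM, and the translation elongation factor genes EEF2 and EEF1G at 4492 ± 315 and 2716 ± 72.7 CPM. The most abundant gene, ENSCJAG00000010051, has no symbol and stood at 11904 ± 171 CPM. ENSCJAG00000022192, also without a symbol, had 207698 and 218979 counts in replicates 1 and 2 and 434410 in replicate 3.

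Genes of the core pluripotency list were expressed throughout. All 13 matched members were above 1 CPM, also when adjusted over the list alone. POU5F1, which encodes the transcription factor OCT4, stood at 1044 ± 122 CPM (SD, n = 3). NANOG and SOX2, which act with it in the pluripotency network, stood at 330 ± 17.2 and 245 ± 17.7 CPM. The epithelial adhesion gene EPCAM stood at 878 ± 133 CPM and LIN28B, an inhibitor of let-7 microRNA processing, at 662 ± 167 CPM. The lowest member, DPPA2, stood at 34.4 ± 7.70 CPM. The list median was 8.07 ± 0.08 on the log2 CPM scale, at percentile 100 of 10000 random lists of the same size. Single members varied more than the list median. By the exact conditional binomial test, 6 of 13 were lower in replicate 3 than in replicate 1 and 6 higher. Of 13719 genes with a mean of at least 1 CPM, 5441 were lower and 4228 higher. The excess of members above 1 CPM over other genes had an odds ratio of 8.88 and an adjusted p of 0.214 by Fisher's exact test. The list did not pass that comparison, in which 75.3% of all genes with a symbol were above the level. All 13 of 13 is the most that the list could reach, and its unadjusted Fisher p was only 0.0477. The comparison thus had little room to show an excess in a list of this size, and decides nothing here.

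Of the naive pluripotency list, whose genes mark the preimplantation epiblast and cells that resemble it, 10 of 14 matched members were above 1 CPM. That was 71.4%, against 75.3% of all genes with a symbol, and thus no excess (odds ratio 0.766, adjusted p = 0.816, Fisher's exact test). KHDC3L, a gene of the oocyte and early embryo, stood at 206 ± 38.7 CPM, KLF4 at 156 ± 19.4 CPM and DPPA5 at 129 ± 28.5 CPM (SD, n = 3). TFCP2L1, a transcription factor gene of naive cells, was above the level at 2.73 ± 0.62 CPM. KLF17, at 0.77 ± 0.54 CPM, and ESRRB, at 0.81 ± 0.13 CPM, were not distinguished from 1 CPM. ARGFX, at 0.20 ± 0.12 CPM, and HORMAD1, at 0.012 ± 0.021 CPM, were below it. Without replicate 3, KLF17 was below the level (log2 value −1.13, adjusted p = 0.000287, edgeR quasi-likelihood, with its own spread ignored as in each fit on 2 libraries). The calls adjusted over the list alone had the same counts as those over all genes, with 10 members above and 2 below.

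Of the primed pluripotency list, whose genes mark postimplantation epiblast and conventional primate stem cells, 12 of 13 matched members were above 1 CPM. That was 92.3%, and the excess over other genes did not pass (odds ratio 2.74, adjusted p = 0.342, Fisher's exact test). DNMT3B, the de novo DNA methyltransferase gene, stood at 2688 ± 54.8 CPM and was the most abundant member (SD, n = 3). The secreted Wnt modulator gene SFRP2 stood at 797 ± 143 CPM, ZIC2 at 71.7 ± 2.73 CPM and OTX2 at 21.04 ± 2.02 CPM. CYTL1 was below the level at 0.66 ± 0.06 CPM, a call lost with DESeq2 and without replicate 1 or replicate 2 (adjusted p = 0.0962, 0.216 and 0.222). Its log2 level was −0.60 with 3 libraries, and −0.57 and −0.55 without replicate 1 and replicate 2, in fits that ignore a gene's own spread. Counts adjusted over the list alone were again 12 above.

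The median of the naive list was 3.32 ± 0.15 on the log2 CPM scale, at percentile 31.5 of random lists, and that of the primed list 4.98 ± 0.14, at percentile 84.2. Within each library the naive median was lower, and the difference of naive minus primed was −1.65 ± 0.28 (SD, n = 3, exact sign-flip p = 0.25, the smallest that 3 libraries allow). Among members with at least 10 counts it was −0.96, and with list means in place of medians −2.28. The lists differ in genes and gene lengths, so the difference describes these lists in these libraries.

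**Figure D1:**
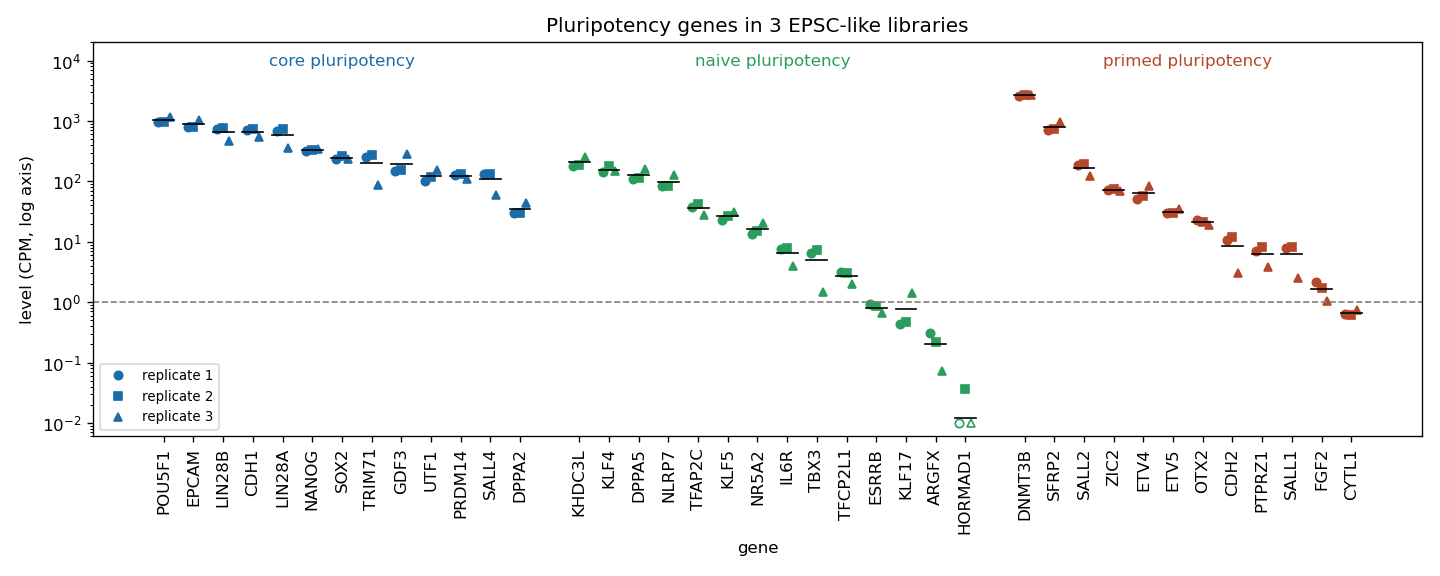
Levels of matched members of the core, naive and primed pluripotency lists, 1 primed member not drawn, in CPM on a log axis, with 1 symbol per library, horizontal bars for the mean of 3 libraries and a dashed line at 1 CPM. Open symbols at the bottom stand for libraries with 0 counts. All 13 core members, 10 of 14 naive members and 12 of 13 primed members were called above the line.

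Genes of the 8-cell stage list, which are switched on when the embryo's genome is activated, were split. SLC34A2, at 61.2 ± 16.9 CPM, and CCNA1, at 13.2 ± 0.60 CPM, were above 1 CPM, while ZNF280A and LEUTX were below it at 0.37 ± 0.22 and 0.033 ± 0.021 CPM (SD, n = 3). DPRX had no counts. The call for ZNF280A was lost without replicate 1 (adjusted p = 0.0506, edgeR quasi-likelihood). Only 5 of the 17 genes listed could be matched, and their median stood at percentile 3.46 of random lists.

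Extraembryonic lists were mixed, and their medians were low among random lists of the same size. They stood at percentiles 4.34 (trophectoderm and trophoblast), 9.97 (primitive endoderm) and 3.64 (amnion). Of the trophectoderm and trophoblast list, 7 of 13 matched members were above 1 CPM, 2 were below, 3 were not distinguished and CYP19A1 had no counts. TEAD3 stood at 26.7 ± 2.44 CPM and the keratin gene KRT7 at 8.63 ± 1.08 CPM (SD, n = 3). TFAP2A was above the level at 12.3, 12.1 and 2.45 CPM in replicates 1, 2 and 3. CDX2, a regulator of trophectoderm, had 25, 29 and 0 counts and was not distinguished from 1 CPM with 3 libraries. TP63 was below the level at 0.049 ± 0.055 CPM. Of the primitive endoderm list, 9 of 13 members were above the level, 3 were not distinguished and AFP had no counts. Its most abundant members encode basement membrane proteins, with COL4A1 at 478 ± 108 CPM, LAMA1 at 181 ± 61.6 CPM and NID2 at 140 ± 41.7 CPM. The endoderm regulator GATA4 was above 1 CPM at 4.21 ± 0.38 CPM. GATA6 was above it as well, but stood at 7.32 and 8.06 CPM in replicates 1 and 2 and at 0.49 CPM in replicate 3. FOXA2, with 32, 98 and 6 counts, was not distinguished from 1 CPM, and its log2 level ran from −1.37 without replicate 2 to 0.26 without replicate 3. Of the amnion list, BAMBI at 10.8 ± 3.48 CPM and GABRP at 2.90 ± 1.47 CPM were above the level. The other 4 of 6 members, TNFRSF11B and WNT6 among them at 0.88 ± 0.09 and 0.54 ± 0.42 CPM, were not distinguished from it.

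The neuroectoderm list was the only one of 28 with an adjusted p under 0.05 by Fisher's exact test at 1 CPM. Its odds ratio of being above 1 CPM was 0.157 (adjusted p = 0.00709). The test takes list members as independent genes, which they are not, so that p may be too small. It also says nothing of the spread between samples. With 75.3% of genes with a symbol above the level, the comparison could show a deficit more easily than an excess. Of its 16 matched members, 10 were below the level. The 5 above it were NES at 336 ± 28.3 CPM and TUBB3 at 105 ± 12.6 CPM, which encode cytoskeletal proteins, NCAM1 at 4.41 ± 2.23 CPM, MAP2 at 4.33 ± 2.27 CPM and PAX6 at 1.71 ± 0.26 CPM (SD, n = 3). SIX6, a regulator of eye development, was the lowest tested member at 0.012 ± 0.021 CPM. Of the primitive streak and mesoderm list, 5 of 11 members were above the level. These were the growth factor receptor genes KDR and PDGFRA at 28.7 ± 0.67 and 7.39 ± 3.21 CPM, TBXT, which encodes brachyury, at 6.16 ± 1.54 CPM, MIXL1 at 2.51 ± 0.57 CPM and TBX6 at 2.22 ± 0.37 CPM. MESP1 was below it at 0.13 ± 0.10 CPM, and MSGN1 and FGF17 had no counts. Of the definitive endoderm list, 6 of 10 members were above, led by KIT at 14.4 ± 4.41 CPM, and the Wnt target gene LGR5 was below at 0.33 ± 0.10 CPM.

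Of the germ cell list, 7 of 10 members were above 1 CPM, with TFAP2C at 35.9 ± 7.19 CPM and DND1 at 13.7 ± 3.17 CPM (SD, n = 3), and TDRD9 was below at 0.33 ± 0.11 CPM. Of the mesenchyme and fibroblast list, 12 of 13 members were above and SNAI2 was not distinguished. The collagen genes COL1A1 and COL1A2 stood at 489 ± 74.96 and 42.2 ± 15.3 CPM, and TAGLN at 62.2 ± 1.37 CPM. Of the blood and endothelium list, PECAM1 at 101 ± 30.5 CPM, SPI1 at 4.22 ± 0.91 CPM, TEK at 2.51 ± 0.12 CPM and VWF at 2.25 ± 0.69 CPM were above the level. They made 4 of 9 members, and PTPRC, the pan-leukocyte gene, was below at 0.037 ± 0.036 CPM. Of the cardiac and skeletal muscle list, 3 of 7 members were above, namely ACTN2, ACTC1 and TNNT2 at 9.58 ± 1.43, 5.87 ± 0.80 and 3.68 ± 0.07 CPM, and MYOD1 was below at 0.038 ± 0.066 CPM. The core pluripotency median exceeded that of each of the 11 lineage and stage lists in each library. The differences ran from 4.30 ± 0.72 log2 units for mesenchyme and fibroblast to 10.28 ± 0.74 for neuroectoderm (SD, n = 3, exact sign-flip p = 0.25 for each, the smallest possible, and 0.25 after adjustment over 12 list comparisons). That over the 8-cell stage list was 9.69, and 4.34 among members with at least 10 counts.

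**Figure D2:**
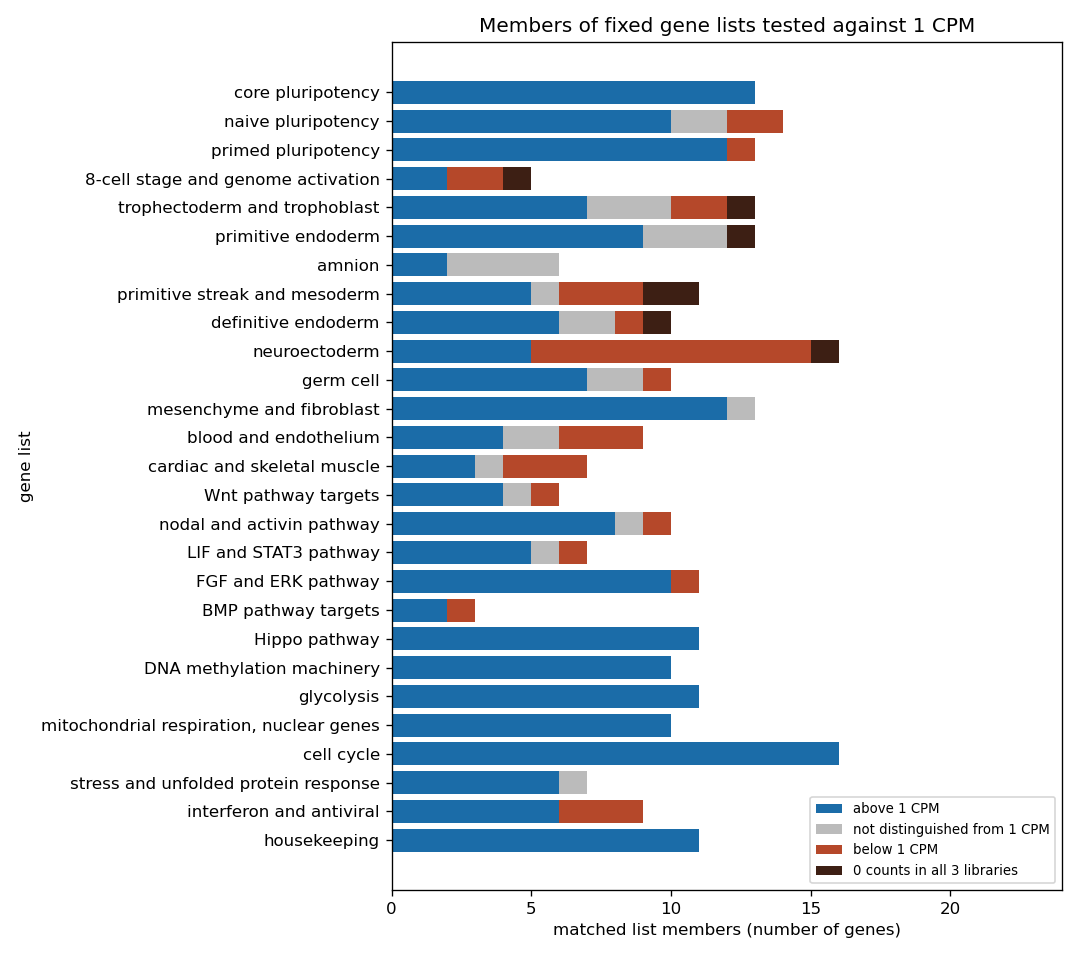
Number of matched members of the fixed gene lists, 1 list not drawn, called above 1 CPM, below it, or not distinguished from it, and of members with 0 counts in the 3 libraries. The neuroectoderm bar has 10 of 16 members below the level, and the cell cycle bar has all 16 above it.

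Of the FGF and ERK list, 10 of 11 matched members were above 1 CPM. The receptor genes FGFR1, FGFR4 and FGFR2 stood at 715 ± 90.4, 105 ± 2.55 and 73.8 ± 14.4 CPM (SD, n = 3), and SPRY2 was below the level at 0.65 ± 0.08 CPM. Of the nodal and activin list, 8 of 10 members were above, with the receptor genes ACVR1B and ACVR2A at 47.8 ± 7.87 and 21.3 ± 1.99 CPM and SMAD2 at 28.1 ± 8.03 CPM. INHBE was below at 0.57 ± 0.09 CPM. Of the LIF and STAT3 list, 5 of 7 members were above, namely STAT3 at 81.8 ± 25.8 CPM, IL6ST at 52.98 ± 15.2 CPM, JAK1 at 37.9 ± 3.67 CPM, JAK2 at 17.3 ± 2.89 CPM and LIFR at 3.89 ± 2.69 CPM. LIF itself was below at 0.49 ± 0.04 CPM. Of the Wnt target list, 4 of 6 members were above, namely NOTUM, TCF7, LEF1 and NKD1 at 13.6 ± 1.27, 10.5 ± 1.18, 2.68 ± 1.52 and 2.08 ± 0.41 CPM. Of the BMP target list only 3 of 10 genes were matched. BMPR1A, which encodes a receptor and is not itself a target, stood at 102 ± 17.6 CPM. BAMBI was above the level as well, and MSX1 was below it at 0.19 ± 0.20 CPM. All 11 members of the Hippo list were above, led by CCN1 at 305 ± 27.0 CPM, YAP1 at 96.1 ± 30.0 CPM and AMOTL2 at 92.0 ± 11.8 CPM. Its lowest member, ANKRD1, had 198, 216 and 13 counts, and its call was lost with DESeq2 (adjusted p = 0.112). The calls for SPRY2 and INHBE were lost without replicate 1 (adjusted p = 0.223 and 0.0652, edgeR quasi-likelihood) and without replicate 2 (0.125 and 0.105).

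All matched genes of the glycolysis, mitochondrial respiration, cell cycle and DNA methylation lists were called above 1 CPM. All 11 glycolysis members passed, with PKM at 1945 ± 27.8 CPM, GAPDH at 1372 ± 163 CPM, ENO1 at 1347 ± 32.7 CPM and the lowest, HK2, at 39.7 ± 12.5 CPM (SD, n = 3). All 10 members of the mitochondrial respiration list were above, with NDUFS1, COX4I1 and UQCRC1 at 380 ± 13.6, 260 ± 31.2 and 217 ± 2.45 CPM. PPARGC1A, a regulator of mitochondrial biogenesis, was the lowest at 1.60 ± 0.64 CPM, and its call was lost without replicate 1 or replicate 2 (adjusted p = 0.125 and 0.133, edgeR quasi-likelihood). All 16 cell cycle members were above, with TOP2A at 1080 ± 139 CPM, MKI67 at 393 ± 58.0 CPM, MCM2 at 312 ± 40.4 CPM and the lowest, CCNE2, at 10.1 ± 1.65 CPM. All 10 members of the DNA methylation list were above. After DNMT3B they were led by TRIM28 at 1725 ± 49.2 CPM and DNMT3A at 339 ± 37.5 CPM, and the lowest, TET2, stood at 8.62 ± 2.28 CPM.

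Of the stress list, 6 of 7 were above 1 CPM, with the chaperone gene HSPA5 at 728 ± 41.0 CPM, ASNS at 133 ± 44.3 CPM and XBP1 at 109 ± 14.4 CPM (SD, n = 3), and TRIB3 was not distinguished at 1.23 ± 0.33 CPM. Of the interferon list, 6 of 9 were above, with BST2 at 31.5 ± 6.94 CPM and IFIT1 at 8.79 ± 2.95 CPM. OAS1 was below at 0.048 ± 0.029 CPM. All 11 housekeeping members were above, from RPLP0 at 2640 ± 185 CPM and YWHAZ at 1056 ± 102 CPM to HPRT1 at 30.5 ± 1.16 CPM. In each of the 28 lists, the counts adjusted over the list alone equalled those adjusted over all genes.

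The replicates were not equally close to each other. Between replicates 1 and 2, 1606 of 23432 genes, or 6.85%, differed by more than the noise of independent counts (exact conditional binomial test, Benjamini-Hochberg adjusted). With counts halved, as if both mates of each read pair had been counted, the number was 239. That number may be too low if only some pairs were counted so. Replicate 3 differed from replicate 1 in 10760 genes and from replicate 2 in 10859 genes, or 45.9% and 46.3%. With a difference of at least 1.5-fold required as well, the counts were 250, 3805 and 3924. Over 13701 genes with a mean of at least 50 counts, the SD of the log2 ratio was 0.161 between replicates 1 and 2, 0.557 between replicates 1 and 3 and 0.561 between replicates 2 and 3. The chi-square per degree of freedom between replicates 1 and 2 was 2.12 in genes with at least 20 and under 100 counts in the pair, 3.59 over genes with at least 20 counts and 8.90 in genes with at least 10000 counts. Replicates 1 and 2 were kept as separate libraries. No label shows whether they are repeats of 1 sample. If they are, there are fewer than 3 independent samples, and the p-values and SDs over 3 libraries may be too small. The common biological coefficient of variation was 0.197. It was 0.0321 without replicate 3.

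The 10 genes of largest dispersion had at most 4 counts in replicate 3. CD226, which encodes an activating receptor of lymphocytes, had 428, 409 and 0 counts, and was at least 101-fold higher in replicates 1 and 2 than the limit of 3 counts in replicate 3. It was called above 1 CPM, a call lost with DESeq2 (adjusted p = 0.263). BMP5 had 118, 102 and 0 counts and ATP6V0D2 146, 175 and 4 counts, and neither was distinguished from 1 CPM with 3 libraries. The other 7 genes have no symbol.

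**Figure D3:**
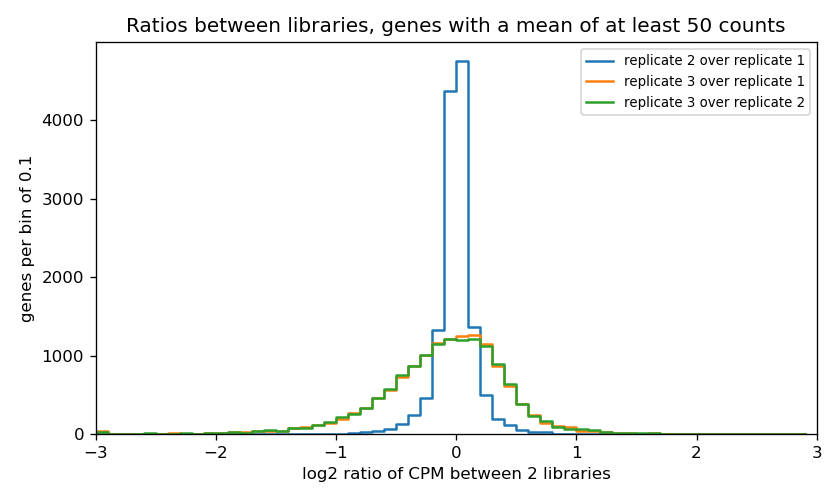
Number of genes per bin of 0.1 in the log2 ratio of CPM between 2 libraries, for the 13701 genes with a mean of at least 50 counts. Ratios below −3 or above 3 are in the end bins. The ratio of replicates 2 and 1 is narrow (SD 0.161), and both ratios with replicate 3 are wider (SD 0.557 and 0.561).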

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

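No paired analysis was possible because there is 1 group. Length-scaled values (TPM) were not run, as no gene lengths of the annotation counted were at hand. The sum of replicates 1 and 2, halved counts and the conditional odds ratio were chosen after seeing the data. Genes above 1 CPM numbered 12974 (without replicate 1) to 13318 (without replicate 3), against 13129. Those above 2 CPM numbered 12047 and those above 0.5 CPM 14153. The neuroectoderm list stayed past the threshold in each alternative, and list differences kept their direction. With 2 libraries (3 leave-one-out fits and the sum of replicates 1 and 2) the prior degrees of freedom were infinite, so a gene's own spread was ignored. A call kept or gained there, such as those for GATA6 and CDX2, is no evidence of stability. Nor is a call lost there evidence that the gene itself varies. The cause was not tested where the construction of an alternative does not show it.

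Moving the level shifts each log2 value by construction. At 0.5 CPM, log2 levels turned for CYTL1 (0.40), FOXA2 (0.78), TNFRSF11B (0.81), WNT6 (0.13), INHBE (0.19), SPRY2 (0.38), KLF17 (0.60), ESRRB (0.70) and ENSCJAG00000005806 (0.95). Without a turn, ZNF280A, LGR5, TDRD9, LIF and MSX1 lost their calls below the level. Odds ratios turned for primitive endoderm (1.21), germ cell (1.67) and LIF and STAT3 (1.14). At 2 CPM, log2 levels turned for SNAI2 (−0.42), PPARGC1A (−0.32), TRIB3 (−0.70), PAX6 (−0.23), BMP5 (−0.53), ENSCJAG00000019348 (−0.23), ENSCJAG00000020654 (−0.89), ENSCJAG00000008173 (−0.75), ENSCJAG00000016710 (−0.76) and ENSCJAG00000019549 (−0.080). Without a turn, GABRP, TEK, LEF1, ANKRD1, CD226, VWF, NKD1, MIXL1 and TBX6 lost their calls above the level. Members above fell to 1 (amnion), 3 (streak and mesoderm), 2 (blood) and 2 (Wnt). Odds ratios for streak and mesoderm (0.171), blood (0.138) and cell cycle (13.8) passed the threshold. With the conditional estimate, the naive and LIF lists also turned at 2 CPM (1.04 each).

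Genes below 1 CPM numbered 3999 with at least 10 counts and 16236 with all genes, from 8851, since fewer or more genes were tested. Without the 10 most abundant genes in the library sizes, ENSCJAG00000005806 turned to 0.029. With replicates 1 and 2 summed, ENSCJAG00000020654 (−0.24), ENSCJAG00000008173 (−0.10) and ENSCJAG00000016710 (−0.11) turned. The naive median was 4.02 with members of at least 10 counts and 2.81 as a mean. Genes that differ by 1.5-fold numbered 250, 3805 and 3924, from 1606, 10760 and 10859. With counts halved and no fold minimum, the 1606 between replicates 1 and 2 fell to 239.

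Leaving out each replicate gave a primitive endoderm odds ratio of 0.715 to 1.44 and log2 levels of −1.37 to 0.26 (FOXA2), −0.082 to 1.03 (BMP5), −0.31 to 0.67 (ENSCJAG00000020654), −0.60 to 0.51 (ENSCJAG00000005806), −0.37 to 0.80 (ENSCJAG00000008173) and −0.27 to 0.79 (ENSCJAG00000016710). The highest value of each came without replicate 3. The coefficient of variation was 0.0321 without replicate 3 and 0.247 without replicate 1. CYTL1, INHBE, SPRY2 and PPARGC1A lost their calls without replicate 1 or 2 or with both summed, and ZNF280A without replicate 1. With DESeq2, CYTL1, SPRY2, ANKRD1, CD226 and ENSCJAG00000009817 lost theirs, as did CYTL1 and SPRY2 without the 10 most abundant genes. Depth limits levels under 0.0546 to 0.0736 CPM, by library.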

Other observations

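Except for the pair test per gene, the tests in this part were chosen after the data were seen. Over the 13719 genes with a mean of at least 1 CPM, 5441 were lower in replicate 3 than in replicate 1 and 4228 higher by the exact conditional binomial test. Of 57 ribosomal protein genes, a group chosen after the data were seen and not tested for enrichment, 49 were higher in replicate 3 than in replicate 1 and 5 lower, with a median log2 ratio of 0.34. Against replicate 2, 47 were higher and 6 lower, with a median of 0.35. Between replicates 1 and 2, 31 were higher in replicate 1 and 3 in replicate 2, with a median log2 ratio of replicate 2 to replicate 1 of −0.04. Of the fixed lists, several had members lower in replicate 3 than in replicate 1 and 0 higher. The numbers lower were 12 of 13 for mesenchyme and fibroblast, 10 of 11 for Hippo, 9 of 11 for primitive endoderm and 5 of 5 for LIF and STAT3, and these lists were not tested against other genes. Of 6 interferon list members, 5 were higher in replicate 3 than in replicate 1 and 1 was lower, while against replicate 2, 3 were higher and 1 was lower.

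The counts of replicate 3 stood apart from those of replicates 1 and 2. A difference in read depth is argued against, since with each library thinned to the same total the pairs with replicate 3 still had at least 10.4 times as many genes that differ. Fewer reads from long messenger RNAs in replicate 3, as RNA fragmentation or another library preparation could give, is a candidate explanation. Of 41 genes of a list of long messenger RNAs, 90.2% were lower in replicate 3 than in both others, against 50.6% of 13719 genes. That idea came from other long genes in these data, and the list's own values were seen only in the test. More cells of other lineages in replicates 1 and 2 could not be decided. Lineage lists with fewer than 5 members at a mean of at least 1 CPM were left out. Of the other 7, 6 lay below the median of all genes in replicate 3, and the germ cell list (0.09) did not. In those 6, the median log2 ratio of replicate 3 to the others ran from −0.84 (primitive endoderm) to −0.21 (neuroectoderm). It was −0.74 for trophectoderm and trophoblast, against −0.48 for the long list. Some lists that name no lineage were also low, with median log2 ratios of replicate 3 to replicate 1 of −0.82 (LIF and STAT3) and −0.22 (cell cycle). All genes stood at −0.05, and other such lists were higher, as naive pluripotency (0.25) and housekeeping (0.15) were. A low median was thus not particular to lineage lists, and the comparison cannot decide this account. It stays open beside a loss of long messenger RNAs. Separate cultures also stay open. The labels name no batch and no biological difference between the replicates, so none was tested.

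The 10 genes of largest dispersion had at most 4 counts in replicate 3. Whether a loss of long messenger RNAs accounts for them stays open. All 10 lay further below the other replicates than the lowest gene of the long list (log2 −1.33, against −4.28 or less), but they were picked for their dispersion, so the comparison decides nothing. CDX2, with 25, 29 and 0 counts, and GATA6, with 383, 443 and 20, also stood far lower in replicate 3, and what these genes share was not tested.

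Even counts outnumbered odd counts among genes with low counts. Among genes with 1 to 10 counts, the share of even counts was 59.0%, 58.5% and 57.1% in replicates 1, 2 and 3, with exact 95% intervals of 57.6 to 60.4%, 57.0 to 59.9% and 55.7 to 58.5%. Among genes with more than 200 and up to 1000 counts the shares were 50.6%, 49.9% and 50.8%. This is consistent with both mates of some read pairs having been counted as 1 read each. If so, the limits set by 0 counts are too low, and the numbers of genes that differ between libraries too high. With counts halved they were 239, against 1606, for replicates 1 and 2, and 8264 and 8423, against 10760 and 10859, for replicate 3 with replicates 1 and 2. Halving treats all reads as counted pairs, while odd counts remained common, so the numbers with counts halved may be too low.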
